A study of Mus musculus with 5 samples.

How the data were processed

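Fibroblasts from mouse lung had received TGF-β1 at 5 ng/mL for 24 h (3 libraries) or vehicle (2 libraries). Per the labels' protocols, RNA was extracted with RNAiso Plus, an acid phenol reagent, and strand-specific polyA mRNA libraries were made with a Vazyme VAHTS stranded kit. The authors deposited 1 table of whole-number counts per gene for the 5 libraries, with 55335 Ensembl gene IDs and no scaling between libraries. The submitters' processing notes name STAR 2.5.3a, an aligner, StringTie 1.3.1c, a transcript assembler that can also give gene counts, and the mouse build mm10, without saying which step used which tool. The counting tool, its strand setting, the annotation release and whether a count stands for a read or a read pair are not given in the sources used here. Multi-mapping reads may have been dropped or shared by that step, so named genes with near-identical copies are reported as uncertain. So are those with an exon overlap with another gene counted at over 0.1 of their own level. Overlaps with scarcer or untested genes are not marked.

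Columns were assigned to samples by their titles, and samples to groups by the same titles and the series design. Gene IDs were matched to GENCODE release M21 (GRCm38, the assembly called mm10), which gave symbols and coordinates for 55154 IDs. The 181 IDs without a symbol held at most 0.00374% of a library's counts and stayed in the tests. Symbols are those of that release (Ddx58, Aars, Ero1l and Pycrl are older names). Coordinates are 1-based and span the whole gene, whose reads come from its exons.

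Genes were filtered with filterByExpr by group and scaled with TMM, with factors of 1.04 and 1.05 for the controls and 0.972, 0.974 and 0.973 for the TGF-β1 libraries. The 16380 genes kept, 13703 of them protein-coding, were tested with edgeR's quasi-likelihood F test on the model of group alone, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors (SE) of the log2 fold change were worked back from the test, as its absolute value over the square root of the F statistic. An exact permutation of 2 against 3 libraries cannot go below a p of 0.1, so single-gene p-values rest on the spread shared across genes. Log2 CPM for correlations and principal components used a prior count of 2. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

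Before the data were examined, 24 gene lists and 7 marker lists were fixed with 973 entries, all matched to IDs. The 29 with at least 5 tested members were tested with camera, which compares a list's genes with the other genes, at a preset inter-gene correlation of 0.01 and adjusted over the 29. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were run beside it. Each list's count is also given with p-values adjusted over the list alone.

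The rule for named genes was fixed at the same time. It took 9 genes in every case, then the 8 largest increases and 8 largest decreases in fitted fold change. These needed an adjusted p under 0.05, a mean of at least 5 CPM, every TGF-β1 library on 1 side of both controls and a proper gene symbol. Up to 3 further members per list with an adjusted p under 0.05 and a mean of at least 5 CPM were added by size of change. Where no member qualified, the most abundant member was named. Genes named outside the rule are said to be chosen after their values were seen.

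The model was tested on simulated counts drawn from the means, dispersions and library sizes of the 16380 genes, with 200 genes changed. For the TGF-β1 against control design, edgeR recovered 14 of 50 genes changed 1.25-fold (28%) and 29 of 50 at 1.5-fold (58%). At 2-fold it recovered 38 of 50 (76%) and at 4-fold 45 of 50 (90%). It also called 17 unchanged genes. False calls thus made up a larger share of the calls in this run than the threshold on the adjusted p aims at. Of 20 simulated lists of 30 genes with 1 shifted, camera at both correlations and fry called the shifted list and 0 others. Simulated genes were drawn independently of each other, so this run cannot show how often correlated lists are falsely called. Libraries held 34283288 to 43163967 counts, and the common biological coefficient of variation was 0.0765.

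Alternatives were fixed before the data were examined: median-of-ratios, upper-quartile and library-total scaling, no filter or over 1 CPM in at least 2 libraries, DESeq2, limma-voom, a test against a 1.5-fold change, the replicate number as a block, and leaving out each library in turn. Leaving out a control leaves 1 control, which is then assumed to vary like the TGF-β1 group. Chi-square statistics between libraries used genes with at least 20 counts over the pair. The figure of mesothelial and interferon genes uses a pseudocount of 0.5 CPM. The floor for a gene with 0 counts in a group was 3 counts over that group, which covers counting error only. Exons of Adamts9, Aldh1l2, Ccnd1, Nusap1, Smpd3 and mt-Nd6 overlap those of another gene on the opposite strand, so their values may depend on that unknown strand setting. No library or gene was left out of the main test apart from the low-count filter.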

Results

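Primary lung fibroblasts, the matrix-producing mesenchymal cells grown out of mouse lung, were cultured with TGF-β1 at 5 ng/mL for 24 h or with vehicle. TGF-β1 is a secreted cytokine that acts through SMAD transcription factors and is widely used to turn cultured fibroblasts into matrix-secreting myofibroblasts. Messenger RNA was sequenced from 2 vehicle control libraries and 3 TGF-β1 libraries, which the series describes as independent biological replicates. The sources used here do not say whether these came from separate animals or from separate dishes, so p-values measure the spread between these 5 libraries. Library totals were 34283288 and 40245128 counts in the controls and 41413098, 43163967 and 39769301 counts with TGF-β1. Between 21045 and 21730 genes had at least 1 count in a library. Pearson correlations of log2 CPM, the counts scaled to library size, were 0.987 to 0.989 within groups and 0.958 to 0.960 between groups, and the first principal component separated the groups with 70.7% of the variance. Replicates of 1 group differed beyond sampling noise, with a chi-square statistic of 4.06 to 8.47 per degree of freedom against 145 to 160 between groups. TGF-β1 replicate 3 stood apart from replicates 1 and 2, with statistics of 8.47 and 8.41 against 4.06 between those 2. On the second principal component (11.4% of the variance) it lay at 35.9, and replicates 1 and 2 lay at −10.6 and −24.5. Gene levels are TMM-normalized CPM as mean ± SD, with n = 2 for control and n = 3 for TGF-β1, and log2 fold changes are TGF-β1 over control. Adjusted p-values for genes come from edgeR's quasi-likelihood test.

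The comparison addressed which transcripts differ after 24 h of TGF-β1. Of 16380 genes tested, 3488 were higher and 3799 were lower with TGF-β1 at an adjusted p under 0.05, and 9093 did not pass. Large changes were more often decreases: 522 genes rose and 1268 fell at least 2-fold, and 180 rose and 448 fell at least 4-fold. The largest increase by the naming rule was in Il11, the cytokine interleukin-11 (ENSMUSG00000004371 on chromosome 7, 4772373 to 4782859 of GRCm38), which rose from 2.00 ± 0.0711 to 64.5 ± 0.866 CPM (log2 fold change 5.01, SE 0.074, adjusted p = 1.57e-10). Eln, encoding elastin (ENSMUSG00000029675 on chromosome 5, 134702593 to 134747323), rose from 13.1 ± 1.24 to 382 ± 8.18 CPM (log2 fold change 4.88, SE 0.058, adjusted p = 4.97e-11). Next came Cdh6, a cadherin, from 0.505 ± 0.0411 to 13.3 ± 1.11 CPM (log2 fold change 4.72), C1qtnf3, a secreted C1q and TNF-related protein, from 0.495 ± 0.0946 to 12.7 ± 0.649 CPM (log2 fold change 4.69), and Aldh1a3, a retinaldehyde dehydrogenase, from 1.37 ± 0.185 to 31.2 ± 2.00 CPM (22.6-fold). Rph3a, Odaph and Acsbg1 rose from under 1 CPM to 16.6 ± 0.498, 10.8 ± 1.62 and 13.4 ± 0.960 CPM, with log2 fold changes of 4.47, 4.42 and 4.31.

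The largest decrease was in Angptl7, a secreted angiopoietin-like protein (ENSMUSG00000028989 on chromosome 4, 148495183 to 148500460), which fell from 882 ± 73.0 to 2.20 ± 0.448 CPM (log2 fold change −8.65, SE 0.093, adjusted p = 3.79e-11), or 402-fold. Smpd3, a neutral sphingomyelinase, fell from 80.3 ± 0.657 to 1.21 ± 0.507 CPM (log2 fold change −6.05), with an exon overlap with Prmt7 on the opposite strand that leaves its value uncertain, Dpysl5 from 16.6 ± 0.0754 to 0.302 ± 0.235 CPM (log2 fold change −5.78), and Steap4, a metalloreductase, from 59.7 ± 1.35 to 1.55 ± 0.0334 CPM (log2 fold change −5.26). Igfbp5, an insulin-like growth factor binding protein, fell from 38.2 ± 0.716 to 1.06 ± 0.159 CPM (log2 fold change −5.17). Clca3a1 fell from 20.4 ± 2.16 to 0.622 ± 0.222 CPM (log2 fold change −5.03), a value left uncertain by its near-identical neighbour Clca3a2. Muc16 and Cldn15 are on the mesothelial marker list and fell from 21.01 ± 2.47 to 0.648 ± 0.101 CPM (log2 fold change −5.02) and from 12.4 ± 0.315 to 0.397 ± 0.351 CPM (log2 fold change −4.98). The 7287 calls were split 47.9% higher to 52.1% lower with TMM scaling, and with library totals alone the higher share was 32.1%, with a median shift of −0.10 in log2 fold change. Many calls were small, 4196 of them under 1.5-fold, and against a null of 1.5-fold 563 genes were higher and 1223 lower.

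Genes of the TGF-β response and feedback list rose as a group, and the inhibitors and receptors in the list did not all move alike. Ccn2, a matricellular growth factor (ENSMUSG00000019997 on chromosome 10, 24595442 to 24598683), rose from 1396 ± 56.9 to 3590.0 ± 167 CPM (log2 fold change 1.36, SE 0.040, adjusted p = 9.19e-09). Smad7, the inhibitory SMAD (ENSMUSG00000025880 on chromosome 18, 75367529 to 75395935), rose from 63.7 ± 3.08 to 86.6 ± 2.82 CPM (log2 fold change 0.44, SE 0.051, adjusted p = 9.94e-05), and Tgfb1 itself (ENSMUSG00000002603 on chromosome 7, 25687002 to 25705077) rose from 73.4 ± 3.41 to 155 ± 1.23 CPM (log2 fold change 1.08, SE 0.042, adjusted p = 6.97e-08). Inhba, encoding the activin A subunit, rose from 235 ± 5.43 to 1573 ± 29.8 CPM (log2 fold change 2.74), and Nox4, an NADPH oxidase, rose from 17.2 ± 0.726 to 66.6 ± 1.88 CPM (log2 fold change 1.95). Tgfbr3, the co-receptor betaglycan, fell from 85.1 ± 0.254 to 17.6 ± 0.464 CPM (log2 fold change −2.28). Of the 41 tested members of this list, 30 were higher, 6 were lower and 5 did not pass (adjusted over the list alone, 31 higher and 6 lower). The list was higher than other genes by camera, with adjusted p = 1.33e-24 over the 29 lists tested. With an estimated inter-gene correlation adjusted p = 0.0404, and this was the only list whose call held with an estimated correlation.

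**Figure D1:**
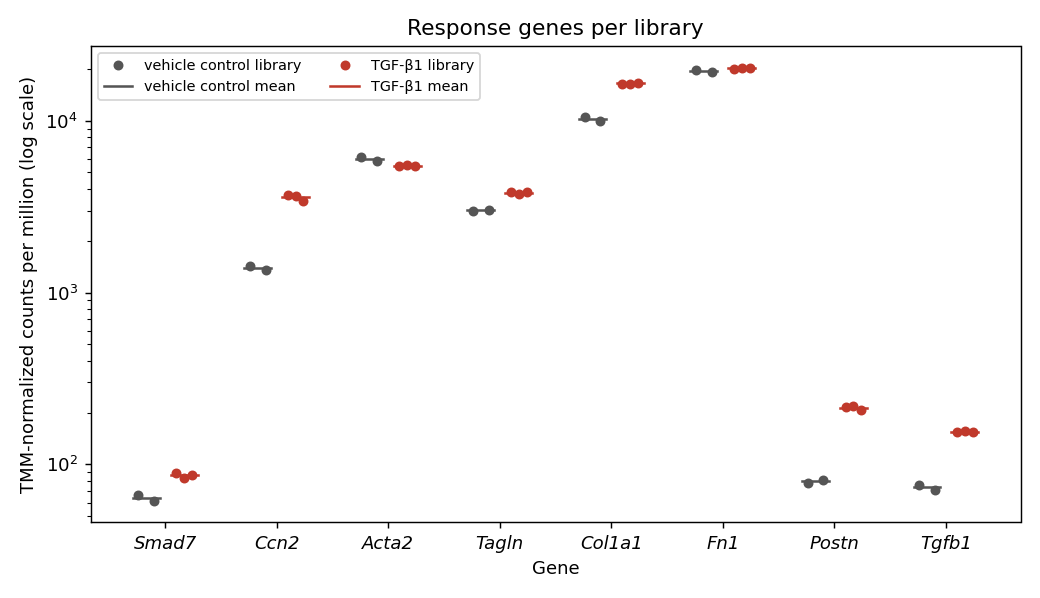
TMM-normalized CPM (log scale) of 8 response genes fixed in advance, with 1 point per library and a line at each group mean, for 2 vehicle control libraries (grey) and 3 TGF-β1 libraries (red). Ccn2, Postn and Tgfb1 were over 2-fold higher with TGF-β1, Smad7, Tagln and Col1a1 under 2-fold, and Acta2 was lower. Fn1 rose by 0.05 on the log2 scale with TMM and was lower by library totals alone.

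Matrix genes changed in both directions within each family. Col1a1, the main fibrillar collagen chain (ENSMUSG00000001506 on chromosome 11, 94936224 to 94953042), rose from 10220.0 ± 316 to 16482 ± 72.7 CPM (log2 fold change 0.69, SE 0.018, adjusted p = 5.27e-09). Col5a3 and Col7a1, a fibrillar collagen and the anchoring-fibril collagen, rose from 19.2 ± 0.276 to 274 ± 5.69 CPM (log2 fold change 3.83) and from 8.46 ± 0.630 to 111 ± 5.89 CPM (log2 fold change 3.71). Col6a2, a chain of the microfibrillar collagen VI, fell from 123 ± 3.32 to 34.7 ± 0.189 CPM (log2 fold change −1.82). Of 30 collagen genes tested, 17 were higher, 9 were lower and 4 did not pass (adjusted over the list alone, 17 higher and 9 lower), and the list was higher by camera with adjusted p = 0.00216. That call ended with an estimated correlation, adjusted p = 0.387, and without the low-count filter, adjusted p = 0.0889.

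Fn1, encoding fibronectin (ENSMUSG00000026193 on chromosome 1, 71585520 to 71653200), was the most abundant of the genes fixed in advance and went from 19534 ± 354 to 20257 ± 151 CPM (log2 fold change 0.05, SE 0.014, adjusted p = 0.0135). Its direction turned with library totals (log2 fold change −0.05), and its call was lost without TGF-β1 replicate 2 (adjusted p = 0.065) and without the low-count filter (adjusted p = 0.0524). Postn, encoding the matricellular protein periostin (ENSMUSG00000027750 on chromosome 3, 54361109 to 54391037), rose from 79.7 ± 1.78 to 214 ± 6.19 CPM (log2 fold change 1.43, SE 0.041, adjusted p = 8.01e-09). Has2, a hyaluronan synthase, rose from 31.1 ± 2.18 to 189 ± 14.7 CPM (log2 fold change 2.60), whereas the leucine-rich proteoglycan Prelp fell from 249.7 ± 3.69 to 30.5 ± 0.814 CPM (log2 fold change −3.03) and the fibulin-family gene Efemp1 fell from 31.1 ± 0.00902 to 4.07 ± 0.643 CPM (log2 fold change −2.93). Among 49 matrix glycoprotein and proteoglycan genes tested, 22 were higher, 20 were lower and 7 did not pass (adjusted over the list alone, 22 higher and 21 lower). The median log2 fold change was 0.03, or −0.07 with library totals, and the list did not pass by camera (adjusted p = 0.162), except without TGF-β1 replicate 3 (adjusted p = 0.0471). Has1 in this list had 0 counts in both controls and was at least 11.3-fold higher against a floor of 3 counts over the control group, and placing it at that bound left the median at 0.03.

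Enzymes that fold, trim and crosslink collagen mostly rose. Lox, a lysyl oxidase that crosslinks collagen and elastin, rose from 1244 ± 21.2 to 2833 ± 70.0 CPM (log2 fold change 1.19). Bmp1, a procollagen C-proteinase, rose from 682 ± 14.8 to 1430.4 ± 14.3 CPM (log2 fold change 1.07), and its enhancer gene Pcolce2 rose from 19.96 ± 3.35 to 73.4 ± 0.845 CPM (log2 fold change 1.88). Of 32 genes tested, 24 were higher, 5 were lower and 3 did not pass (adjusted over the list alone, 25 higher and 5 lower). The list was higher by camera with adjusted p = 1.38e-11, and adjusted p = 0.0685 with an estimated correlation.

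Matrix proteases and their inhibitors split. The aggrecan-cleaving proteases Adamts9 and Adamts5 fell from 73.5 ± 1.87 to 6.79 ± 0.467 CPM (log2 fold change −3.44) and from 91.4 ± 0.304 to 13.7 ± 0.788 CPM (log2 fold change −2.74), and the collagenase Mmp8 fell from 20.1 ± 0.721 to 1.95 ± 0.428 CPM (log2 fold change −3.36). Adamts9 is uncertain, as its exons overlap A730049H05Rik on the opposite strand. Of 41 genes tested, 16 were higher, 22 were lower and 3 did not pass (adjusted over the list alone, 16 higher and 22 lower), with adjusted p = 0.745 by camera.

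In the cartilage and tendon list, Col11a1, a fibrillar collagen chain, rose from 326 ± 14.5 to 1089.5 ± 12.7 CPM (log2 fold change 1.74), Acan, encoding the proteoglycan aggrecan, rose from 7.96 ± 1.12 to 24.3 ± 0.501 CPM (log2 fold change 1.61), and Runx1, a transcription factor best known from blood cell development, rose from 93.9 ± 1.71 to 193 ± 10.2 CPM (log2 fold change 1.04). Of 20 members tested, 9 were higher, 4 were lower and 7 did not pass (adjusted over the list alone, 9 higher and 4 lower), and 6 of its 32 entries also stand in another list. Without control 1, 2 members were lower. The list was higher by camera with adjusted p = 0.0023, and adjusted p = 0.157 with an estimated correlation.

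Contractile genes did not move together. Acta2, encoding the smooth muscle α-actin used as a myofibroblast marker (ENSMUSG00000035783 on chromosome 19, 34241090 to 34255590), was abundant in the controls and went from 5970.2 ± 197 to 5484 ± 34.03 CPM (log2 fold change −0.12, SE 0.020, adjusted p = 0.000994), a decrease of 1.09-fold. Tagln, encoding the actin-binding protein transgelin (ENSMUSG00000032085 on chromosome 9, 45929619 to 45936058), rose from 3006 ± 26.5 to 3798 ± 60.1 CPM (log2 fold change 0.34, SE 0.019, adjusted p = 7.34e-07), and the genes overlapping its exons (Pcsk7 and Gm48529) are too scarce to account for its count. Itgb3, an integrin β chain, rose from 25.9 ± 2.24 to 136 ± 2.26 CPM (log2 fold change 2.40), and Csrp2, a LIM-domain protein of smooth muscle, rose from 21.5 ± 1.65 to 111 ± 6.01 CPM (log2 fold change 2.37). Itga8, the integrin α8 chain, fell from 69.4 ± 4.87 to 9.73 ± 0.902 CPM (log2 fold change −2.83), and Myh11, the smooth muscle myosin heavy chain, fell from 494 ± 6.61 to 317 ± 0.977 CPM (log2 fold change −0.64). Of 49 contractile and cytoskeletal genes tested, 20 were higher, 16 were lower and 13 did not pass (adjusted over the list alone, 22 higher and 18 lower). The median was 0.03, or −0.07 with library totals, and camera gave adjusted p = 0.109, or 0.0437 without TGF-β1 replicate 3.

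Targets of YAP and TEAD, the transcriptional arm of the Hippo pathway, also split. Ankrd1 and the kinase gene Nuak2 rose from 194 ± 11.5 to 626 ± 37.1 CPM (log2 fold change 1.69) and from 10.4 ± 2.11 to 35.3 ± 4.44 CPM (log2 fold change 1.77), while Igfbp3 fell from 279.8 ± 13.5 to 23.2 ± 0.506 CPM (log2 fold change −3.59). Of 24 tested, 8 were higher, 9 were lower and 7 did not pass (adjusted over the list alone, 10 higher and 11 lower). Camera gave a downward direction with adjusted p = 0.745, whereas the median of 0.00 and the mean of 0.05 lay at or just above 0, and with library totals the median was −0.10.

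Genes of resting lung fibroblast states were lower on balance. In the alveolar fibroblast and lipofibroblast list, Vegfd, a growth factor for lymphatic vessels, fell from 38.2 ± 0.753 to 2.15 ± 0.0592 CPM (log2 fold change −4.15), Limch1 fell from 27.2 ± 0.842 to 1.58 ± 0.198 CPM (log2 fold change −4.10), and Lpl, the lipoprotein lipase, fell from 88.2 ± 2.93 to 12.3 ± 1.16 CPM (log2 fold change −2.84). Of its 26 tested members, 6 were higher, 13 were lower and 7 did not pass (adjusted over the list alone, 6 higher and 13 lower). The list was lower by camera with adjusted p = 1.88e-10, and adjusted p = 0.0685 with an estimated correlation. In the adventitial and universal fibroblast list, the complement gene C4b, uncertain in value for its near-identical paralog, fell from 19.3 ± 1.93 to 4.49 ± 0.234 CPM (log2 fold change −2.11), Dcn, encoding decorin, from 141 ± 7.13 to 37.7 ± 1.27 CPM (log2 fold change −1.90), and Igfbp4 from 232 ± 0.902 to 67.2 ± 3.02 CPM (log2 fold change −1.79). Of its 26 tested members, 8 were higher, 14 were lower and 4 did not pass (adjusted over the list alone, 8 higher and 15 lower), with adjusted p = 2.72e-05, and adjusted p = 0.0915 with an estimated correlation. Its median log2 fold change was −0.87, also with Has1 at its bound.

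Markers of mesothelium, the cell layer that covers the lung surface, fell in the same libraries as these fibroblast genes. Upk1b, a uroplakin, fell from 492 ± 17.1 to 44.9 ± 2.17 CPM (log2 fold change −3.45, SE 0.044, adjusted p = 6.37e-11). Lrrn4 fell from 175 ± 14.6 to 7.04 ± 0.354 CPM (log2 fold change −4.64) and Gpm6a from 153 ± 4.36 to 8.28 ± 0.697 CPM (log2 fold change −4.21). Of 13 marker genes tested, 1 was higher, 12 were lower and 0 did not pass (adjusted over the list alone, 1 higher and 12 lower), with a median of −1.83. The exception was Aldh1a2, named here after its value was seen, with a log2 fold change of 0.16 and no call with library totals. The list was lower by camera with adjusted p = 6.51e-41, and adjusted p = 0.0685 with an estimated correlation. The 2 controls were alike, with median deviations of 0.03 and −0.03 in log2(CPM + 0.5) from their mean.

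**Figure D2:**
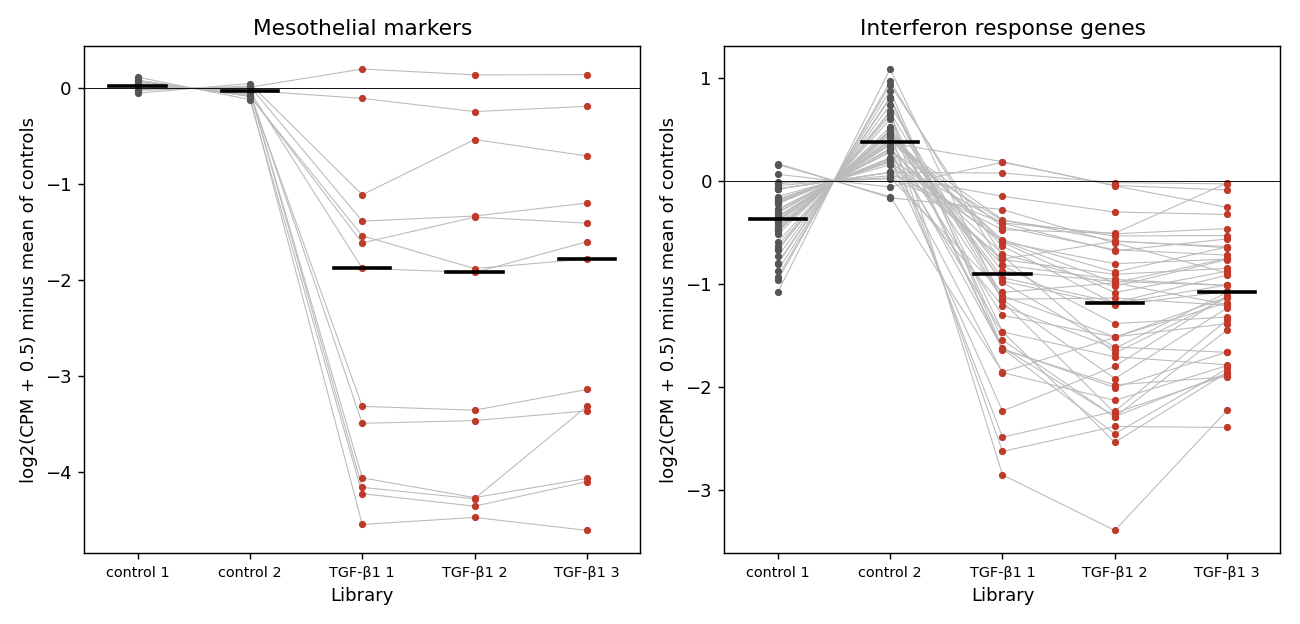
Log2(CPM + 0.5) of each tested gene minus its mean over the 2 controls, by library, for 13 mesothelial markers (left) and 46 interferon response genes (right), with 1 point per gene, a grey line joining each gene across libraries and a black bar at the median. Mesothelial medians were 0.03 and −0.03 in the controls and −1.88, −1.92 and −1.78 with TGF-β1. Interferon medians were −0.37 in control 1, 0.37 in control 2 and −0.91, −1.19 and −1.08 with TGF-β1.

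Interferon response genes were lower with TGF-β1, and the 2 controls also stood apart in them. Ifit1, an interferon-induced RNA-binding protein, went from 14.5 ± 9.26 to 1.51 ± 0.806 CPM (log2 fold change −3.28, SE 0.45, adjusted p = 0.000303), Rtp4 went from 12.8 ± 10.2 to 2.49 ± 0.676 CPM (log2 fold change −2.37), and Usp18, which removes the ubiquitin-like ISG15, went from 11.5 ± 8.64 to 2.30 ± 0.987 CPM (log2 fold change −2.34). Control 2 was above control 1 in 43 of the 46 tested members, by a median log2 ratio of 0.76, against a median of −0.003 over all tested genes. Of the 46, 0 were higher, 41 were lower and 5 did not pass by edgeR (adjusted over the list alone, 0 higher and 41 lower). No member was higher at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 higher each, with 38 and 39 lower. The median was −1.24. Without control 2 it was −0.68 and 23 members were called lower, with Usp18 lost (adjusted p = 0.0577), and without control 1 it was −1.59 with 41 lower. The list was lower by camera with adjusted p = 2.72e-05, and adjusted p = 0.529 with an estimated correlation.

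Inflammatory genes changed in both directions. Ptgs2, encoding the prostaglandin synthase COX-2, rose from 439 ± 1.17 to 2643 ± 43.8 CPM (log2 fold change 2.59, SE 0.023, adjusted p = 2.57e-11). Saa3, an acute-phase protein, fell from 206 ± 18.4 to 6.89 ± 0.743 CPM (log2 fold change −4.90, SE 0.085, adjusted p = 4.64e-10), and Il1rl1, the interleukin-33 receptor, fell from 13.5 ± 3.15 to 2.56 ± 0.489 CPM (log2 fold change −2.40). Of 36 cytokine, chemokine and related genes tested, 11 were higher, 18 were lower and 7 did not pass (adjusted over the list alone, 11 higher and 18 lower), and camera gave adjusted p = 0.26. Leukocyte transcripts were present in all 5 libraries and did not all move alike with the treatment. Marco, a macrophage scavenger receptor, fell from 18.5 ± 1.51 to 3.41 ± 0.409 CPM (log2 fold change −2.44), Cd14, a co-receptor for lipopolysaccharide, fell from 36.2 ± 2.78 to 10.6 ± 1.47 CPM (log2 fold change −1.78), and the lysozyme gene Lyz1 fell from 49.1 ± 0.493 to 24.7 ± 3.36 CPM (log2 fold change −0.99), where reads shared with its near-identical neighbour Lyz2 leave the value uncertain. Of 20 macrophage and leukocyte markers tested, 3 were higher, 12 were lower and 5 did not pass (adjusted over the list alone, 3 higher and 12 lower). The median log2 fold change was −0.19, and only 2 of the decreases reached 2-fold. The list was lower by camera with adjusted p = 0.0023, and adjusted p = 0.154 with an estimated correlation. The 3 higher members, named after their values were seen, were Ptprc, Fcgr3 and Ctss, with log2 fold changes of 0.29, 0.30 and 0.55.

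Cell cycle genes fell together by moderate amounts. Nusap1, a spindle protein, fell from 20.4 ± 1.88 to 8.79 ± 0.563 CPM (log2 fold change −1.21, SE 0.100, adjusted p = 9.98e-06), Ect2, needed for cytokinesis, fell from 32.0 ± 3.55 to 15.1 ± 0.0602 CPM (log2 fold change −1.08), and Cenpf, a kinetochore protein, fell from 20.7 ± 1.61 to 10.6 ± 1.51 CPM (log2 fold change −0.96). Nusap1 is uncertain where it overlaps Oip5 on the opposite strand. Of 55 genes tested, 0 were higher, 50 were lower and 5 did not pass by edgeR (adjusted over the list alone, 0 higher and 50 lower), and only 2 of the decreases reached 2-fold. No member was higher at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 higher and 49 and 50 lower. Without TGF-β1 replicate 3, 1 was higher. The median was −0.70, and camera gave adjusted p = 6.07e-11, or adjusted p = 0.157 with an estimated correlation.

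The p53 and senescence list had no common direction. Cdkn2b, the CDK inhibitor p15, rose from 45.3 ± 0.344 to 118 ± 7.53 CPM (log2 fold change 1.38), Ccnd1, cyclin D1, fell from 107 ± 8.50 to 48.2 ± 5.83 CPM (log2 fold change −1.15), and Sesn1 fell from 32.3 ± 1.26 to 16.5 ± 0.418 CPM (log2 fold change −0.97). Ccnd1 is uncertain where it overlaps LTO1 on the opposite strand. Of 26 tested, 9 were higher, 8 were lower and 9 did not pass (adjusted over the list alone, 12 higher and 9 lower), and without control 1 only 5 were lower. Camera gave adjusted p = 0.586 in the upward direction, with a median of 0.05 (−0.05 with library totals) and a mean of −0.03. Among immediate early genes, Egr2, a zinc-finger transcription factor, rose from 2.49 ± 0.0557 to 18.1 ± 3.93 CPM (log2 fold change 2.86), Nr4a2, an orphan nuclear receptor, rose from 3.41 ± 0.219 to 7.61 ± 1.79 CPM (log2 fold change 1.16), and Klf2 fell from 23.0 ± 1.57 to 8.30 ± 3.86 CPM (log2 fold change −1.46). Of 26 tested, 10 were higher, 4 were lower and 12 did not pass (adjusted over the list alone, 12 higher and 4 lower). Camera gave adjusted p = 0.177, or 0.00384 without TGF-β1 replicate 3.

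Genes of the serine, glycine, proline and ATF4 program list, which includes amino acid transporters, mostly rose. Cth, the enzyme that makes cysteine from cystathionine, rose from 11.5 ± 0.711 to 32.9 ± 1.39 CPM (log2 fold change 1.52, SE 0.077, adjusted p = 3.92e-07). Aldh1l2, a mitochondrial folate enzyme, rose from 77.7 ± 4.18 to 211 ± 5.16 CPM (log2 fold change 1.44), and Slc7a11, the cystine importer, rose from 8.67 ± 0.764 to 19.4 ± 0.305 CPM (log2 fold change 1.16). Aldh1l2 is uncertain where it overlaps D10Wsu102e on the opposite strand. Of 40 serine, glycine, proline and ATF4 program genes tested, 33 were higher, 0 were lower and 7 did not pass by edgeR (adjusted over the list alone, 35 higher and 0 lower). At an unadjusted p under 0.05 the number lower was 0, DESeq2 and limma-voom called 32 higher and 0 lower each, and library totals gave 30 higher and 1 lower. Without TGF-β1 replicate 3, 1 was lower too. The median was 0.60, with adjusted p = 1.3e-14 by camera, or adjusted p = 0.157 with an estimated correlation.

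Endoplasmic reticulum chaperone and secretion genes rose by small steps, none of them 2-fold. Creb3l1 and Creb3l2, membrane-bound transcription factors of the secretory pathway, rose from 171 ± 1.64 to 304 ± 8.76 CPM (log2 fold change 0.83) and from 322 ± 12.7 to 536 ± 10.2 CPM (log2 fold change 0.74), and the disulfide isomerase gene Pdia5 rose from 39.6 ± 1.41 to 69.1 ± 6.89 CPM (log2 fold change 0.80). Of 41 tested, 35 were higher, 1 was lower and 5 did not pass (adjusted over the list alone, 36 higher and 1 lower). The median was 0.37, with adjusted p = 6.6e-11 by camera, or adjusted p = 0.154 with an estimated correlation.

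Glycolysis genes showed no common direction with TMM scaling. The transporter genes Slc2a3 for glucose and Slc16a1 for lactate fell from 10.7 ± 2.09 to 4.15 ± 0.259 CPM (log2 fold change −1.36) and from 30.1 ± 0.0723 to 18.1 ± 1.13 CPM (log2 fold change −0.73), and the aldolase gene Aldoc fell from 7.62 ± 0.823 to 3.90 ± 0.281 CPM (log2 fold change −0.96). Of 25 tested, 7 were higher, 8 were lower and 10 did not pass (adjusted over the list alone, 7 higher and 11 lower), and with library totals 6 were higher and 15 lower. Camera pointed upward with adjusted p = 0.866, while the median was −0.01 and the mean −0.09, and with library totals the median was −0.11 and camera pointed downward (adjusted p = 0.70).

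Cholesterol synthesis genes were mostly lower. Sc5d, a sterol desaturase, fell from 112 ± 1.59 to 71.8 ± 1.70 CPM (log2 fold change −0.64), and Tm7sf2, a sterol reductase, fell from 10.1 ± 1.33 to 5.78 ± 0.115 CPM (log2 fold change −0.80). The value of Tm7sf2 is uncertain because its exons overlap those of the more abundant Vps51 on the same strand. Of 26 tested, 3 were higher, 18 were lower and 5 did not pass (adjusted over the list alone, 3 higher and 19 lower). Camera gave adjusted p = 0.044, lost with an estimated correlation (adjusted p = 0.529), with the stricter filter (adjusted p = 0.0735), without control 1 (adjusted p = 0.0978) and without TGF-β1 replicate 2 (adjusted p = 0.0637).

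Antioxidant and detoxification genes fell in part. Aldh1a1, an aldehyde dehydrogenase, fell from 184 ± 5.72 to 7.63 ± 0.577 CPM (log2 fold change −4.59, SE 0.062, adjusted p = 9.03e-11), the microsomal glutathione transferase gene Mgst1 fell from 135 ± 4.21 to 30.2 ± 4.32 CPM (log2 fold change −2.16), and Sod3, the extracellular superoxide dismutase, fell from 52.3 ± 0.0880 to 13.2 ± 0.434 CPM (log2 fold change −1.99). Of 38 tested, 6 were higher, 18 were lower and 14 did not pass (adjusted over the list alone, 7 higher and 21 lower). Camera gave adjusted p = 2.2e-06, or adjusted p = 0.157 with an estimated correlation. Among the 13 mitochondrially encoded genes, mt-Nd2, mt-Nd1 and mt-Nd6, subunits of respiratory complex I, had log2 fold changes of 0.25, 0.22 and 0.20. Of the 13, 7 were higher, 0 were lower and 6 did not pass by edgeR (adjusted over the list alone, 8 higher and 0 lower). At an unadjusted p under 0.05, 8 were higher and 0 lower, and DESeq2 and limma-voom called 7 and 8 higher and 0 lower. The count was 13 without TGF-β1 replicate 3 and 2 with library totals, where mt-Nd6 was not called, and camera gave adjusted p = 0.162, or 0.0353 without TGF-β1 replicate 3. mt-Nd6 overlaps mt-Nd5 on the opposite strand, and its value is uncertain as the counting's use of strand is not known.

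Several BMP pathway genes were lower. Bmp4, a ligand of the pathway, fell from 40.7 ± 3.00 to 8.86 ± 0.201 CPM (log2 fold change −2.20, SE 0.076, adjusted p = 2.81e-08), Id4, an inhibitor of basic helix-loop-helix factors, fell from 18.5 ± 1.14 to 2.92 ± 0.229 CPM (log2 fold change −2.67), and the transcription factor gene Atoh8 fell from 42.98 ± 0.358 to 12.3 ± 1.38 CPM (log2 fold change −1.81). Of 30 tested, 7 were higher, 16 were lower and 7 did not pass (adjusted over the list alone, 8 higher and 16 lower). Camera gave adjusted p = 0.0521, just over the threshold, and 0.0208 to 0.0493 with each other normalization or without the low-count filter, but 0.0846 with the stricter filter. Leaving out single libraries gave 0.034 to 0.0561, above 0.05 only without control 1, and an estimated correlation gave adjusted p = 0.21.

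WNT pathway genes moved both ways. Lgr6, a receptor for R-spondins, rose from 1.70 ± 0.255 to 20.7 ± 1.45 CPM (log2 fold change 3.61), the ligand gene Wnt11 rose from 5.19 ± 0.519 to 26.6 ± 0.448 CPM (log2 fold change 2.36), and Sfrp1, a secreted WNT antagonist, fell from 486 ± 8.35 to 80.5 ± 1.79 CPM (log2 fold change −2.59). Of 39 tested, 11 were higher, 15 were lower and 13 did not pass (adjusted over the list alone, 12 higher and 17 lower), with adjusted p = 0.328 by camera. Growth factor genes included some of the larger changes. Hbegf and Nrg1, ligands of EGF-family receptors, rose from 26.7 ± 1.80 to 268 ± 21.8 CPM (log2 fold change 3.33) and from 4.74 ± 0.174 to 35.4 ± 1.92 CPM (log2 fold change 2.90), and Kitl, the stem cell factor, fell from 21.8 ± 3.61 to 4.02 ± 0.60 CPM (log2 fold change −2.44). Of 38 tested, 15 were higher, 18 were lower and 5 did not pass (adjusted over the list alone, 15 higher and 18 lower), with adjusted p = 0.976.

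**Figure D3:**
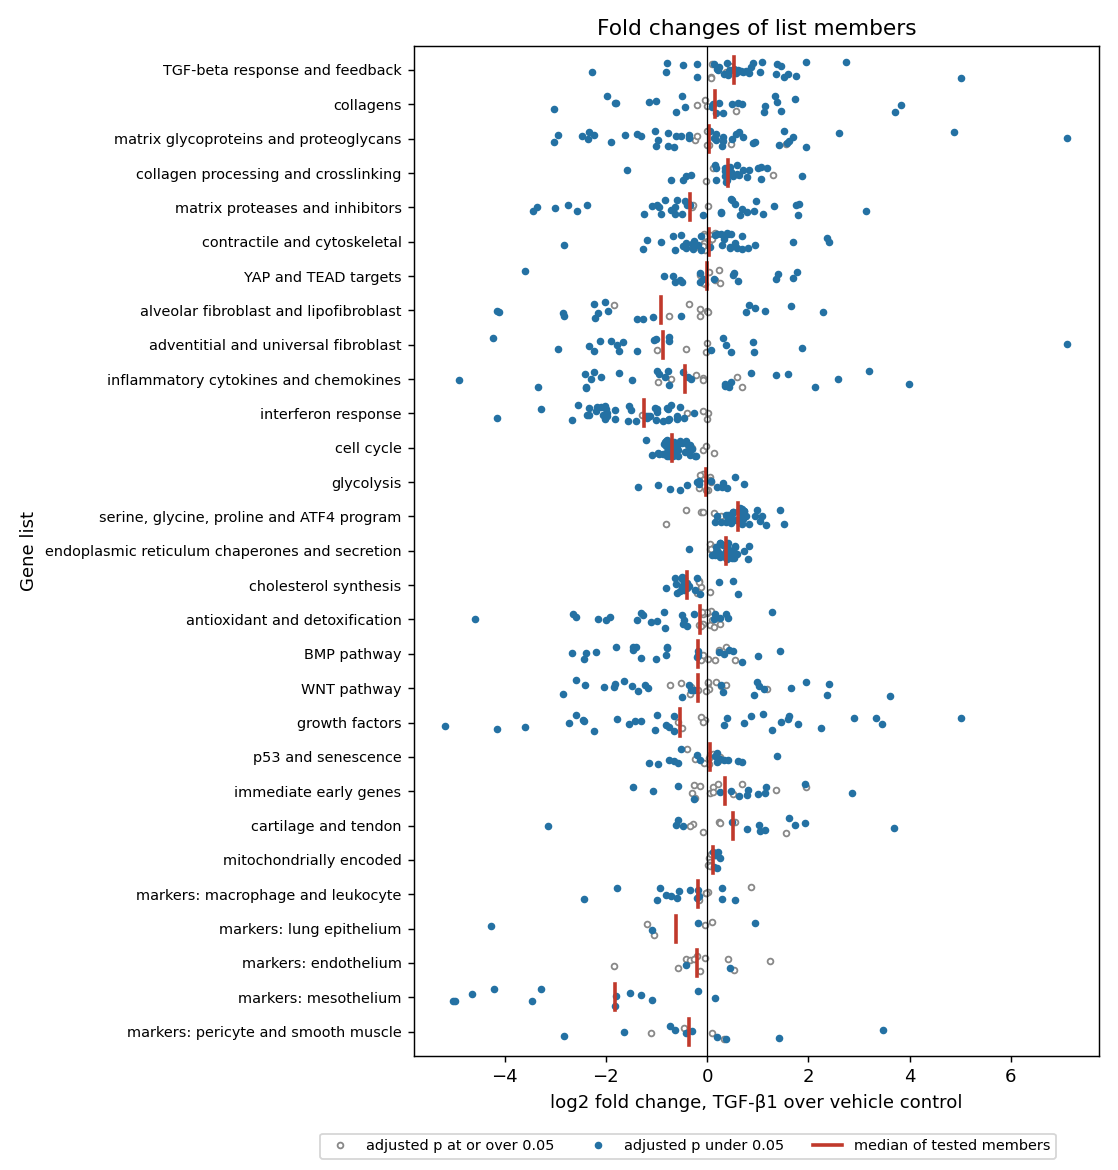
Log2 fold changes (TGF-β1 over vehicle control) of the tested members of the 29 gene and marker lists, with filled points for genes at an adjusted p under 0.05, open points for the others and a red line at each list's median. Interferon, cell cycle and mesothelial medians lie at −1.24, −0.70 and −1.83, and the serine, glycine, proline and ATF4 list at 0.60. The point at 7.11 is the fitted value of Has1, which had 0 counts in both controls and is no bound.

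Transcripts of other lung cell types were scarce. Of 20 epithelial markers only 8 passed the filter. Krt18, a simple-epithelium keratin also on the mesothelial list, went from 50.5 ± 1.14 to 44.6 ± 2.17 CPM (log2 fold change −0.18, adjusted p = 0.0284). Its call was lost without either control, without TGF-β1 replicate 2, with DESeq2 and without the low-count filter, with adjusted p between 0.0539 and 0.166. Of the 8, 1 was higher, 3 were lower and 4 did not pass (adjusted over the list alone, 1 higher and 3 lower), with 1 lower without control 1, and camera gave adjusted p = 0.314. Of 13 endothelial markers tested, 1 was higher, 1 was lower and 11 did not pass (adjusted over the list alone, 1 higher and 1 lower), with adjusted p = 0.976. The number lower was 0 without control 1 or TGF-β1 replicate 1, and 2 without TGF-β1 replicate 3 or with limma-voom. Esam, an adhesion molecule, rose from 20.2 ± 2.49 to 27.5 ± 1.10 CPM (log2 fold change 0.45). Flt1, a VEGF receptor, fell from 16.0 ± 2.24 to 11.9 ± 1.02 CPM (log2 fold change −0.42), a call lost without control 1 (adjusted p = 0.172) and without TGF-β1 replicate 1 (adjusted p = 0.0501). The endothelial median was −0.19 (0.16 without control 2) and the mean −0.12, while camera pointed upward. Il7r was the only lymphocyte marker tested, at 1.23 ± 0.0738 CPM in controls and 0.612 ± 0.202 CPM with TGF-β1 (adjusted p = 0.0407). Its call was lost without either control (adjusted p = 0.121 and 0.178) and without TGF-β1 replicate 2 or 3 (adjusted p = 0.108 and 0.0797). It was also lost with DESeq2 (adjusted p = 0.139), without the low-count filter (adjusted p = 0.0589) and with the replicate number as a block (adjusted p = 0.106).

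Pericyte and smooth muscle markers split. Cspg4, encoding the proteoglycan NG2, rose from 4.31 ± 0.458 to 48.0 ± 2.02 CPM (log2 fold change 3.47), and Notch3 fell from 19.95 ± 0.0681 to 12.0 ± 0.509 CPM (log2 fold change −0.73). Of 14 tested, 4 were higher, 6 were lower and 4 did not pass (adjusted over the list alone, 4 higher and 7 lower). Camera pointed upward with adjusted p = 0.422, whereas the median was −0.35 and the mean −0.16. The 4 sex-linked genes tested, all on the Y chromosome, were at like levels in the 5 libraries. Ddx3y had 99.9 ± 0.776 CPM in controls and 107 ± 4.17 CPM with TGF-β1 (adjusted p = 0.086). Of the 4, 0 were called by edgeR over all genes or adjusted over the list alone, 0 by DESeq2 or limma-voom, and 1 was higher at an unadjusted p under 0.05. Without control 2, 5 were tested and 1 was called lower, the X-linked Xist having entered the test with 0.42 CPM in control 1.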

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

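All alternatives were chosen before the data were examined. The 4 counts of called genes (higher, lower, and each at 2-fold or more) stayed within 1.5 times their values except under 2 settings. With library totals alone, 2325 genes were higher in place of 3488, because the control and TGF-β1 scaling factors lie on opposite sides of 1. Against a null of 1.5-fold change, which removes small changes by construction, 563 were higher and 1223 lower. Of the 7287 called genes, 7261 kept their call with median-of-ratios scaling, 7150 with upper-quartile scaling, 6125 with library totals, 6406 without a filter, 6928 with the stricter filter, 6342 with DESeq2, 7196 with limma-voom and 5259 to 6918 without single libraries. Leaving out a control, which leaves 1, gave 5433 and 5469 calls. The sources used here do not say whether same-numbered cultures were paired. Same-numbered deviations from the group means correlated at only 0.0159 and 0.0161. With 2 controls these deviations mirror each other, so such values show no sign of pairing but cannot exclude it. With the replicate number as a block, 7265 genes were called, 6737 of the 7287 among them. Without TGF-β1 replicate 3, 7504 genes were called, more than the 7287 with all 5 libraries.

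With an estimated inter-gene correlation 13 list calls were lost. Camera's adjusted p was then 0.387 for collagens, 0.0685 for collagen processing, the alveolar list and mesothelium, 0.0915 for the adventitial list, 0.529 for interferon and cholesterol, 0.157 for cell cycle, serine and ATF4, antioxidant and cartilage, and 0.154 for endoplasmic reticulum and macrophage markers. In 2 of these lists, adventitial (−0.0062) and macrophage (−0.0477), the estimate lay under the preset 0.01. The TGF-β response list, estimated at 0.004, also went from 1.33e-24 to 0.0404. A larger correlation cannot account for the shifts of the adventitial, macrophage and TGF-β response lists. In the other lists that lost their call the estimate was above 0.01, from 0.0114 (alveolar) to 0.6344 (interferon). There a larger correlation is not excluded as a reason, but the run cannot separate it from whatever moved the lists with low estimates. The cause was not tested. Fry, which asks no comparison with other genes, put 9 further lists past the threshold: matrix glycoproteins 0.00696, proteases 0.0144, contractile 0.00222, inflammatory 0.00463, BMP 0.000541, WNT 0.00149, immediate early 0.0234, epithelium 0.0115 and pericytes 0.00119. It turned endothelium downward at 0.64.

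For the other changes the cause was not tested. The BMP list (adjusted p 0.0521) passed with median-of-ratios 0.0491, upper-quartile 0.0493, library totals 0.0325, no filter 0.0208 and the replicate block 0.0376, and ranged from 0.034 to 0.0561 without single libraries. Without a filter collagens gave 0.0889 and mitochondrial genes 0.00823, and cholesterol gave 0.0735 with the stricter filter. The block gave 0.00258 for immediate early and 0.0376 for mitochondrial genes. Single libraries left out moved matrix glycoproteins between 0.0471 and 0.38, contractile genes between 0.0437 and 0.184, cholesterol between 0.0136 and 0.0978, immediate early genes between 0.00384 and 0.204 and mitochondrial genes between 0.0353 and 0.246. Lists far from the threshold changed direction: growth factors with median-of-ratios 0.975, the stricter filter 0.923 and the block 0.321; glycolysis with library totals 0.70 and no filter 0.967; YAP and TEAD with no filter 0.988 and the block 0.57; endothelium with no filter 0.879 and the block 0.931; and pericytes with no filter 0.671. Over all 5 left-out libraries growth factors gave 0.392 to 0.991, YAP and TEAD 0.432 to 0.985 and endothelium 0.866 to 0.997. Among these runs, direction changed without TGF-β1 replicates 2 and 3 for growth factors and for YAP and TEAD, and without control 1 and TGF-β1 replicate 3 for endothelium.

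Of the 111 named genes, Fn1 changed direction with library totals, at a log2 fold change of −0.0469. Under each scaling, filter or tool at least 108 kept direction and side of the threshold, and under each left-out library at least 108 did. The test against a 1.5-fold change ended 17 calls. In simulated counts of this depth and replication, 58% of genes changed 1.5-fold were recovered. Far fewer genes were changed in that simulation than were called in the data, and the adjusted p depends on that share. The simulated recovery therefore cannot tell how often changes of that size were missed here.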

Other observations

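All gene families in this part and all tests except that of the interferon genes were chosen after the results were seen. Complement genes were lower in a block: of 16 tested, 13 were lower, 0 were higher and 3 did not pass by edgeR. No member was higher at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 higher and 12 and 13 lower. C3, the central component, fell from 997 ± 9.99 to 298 ± 9.60 CPM (log2 fold change −1.74), C1s1 from 453 ± 4.79 to 193 ± 4.25 CPM (log2 fold change −1.23) and the membrane inhibitor Cd55 from 62.1 ± 0.171 to 11.1 ± 0.388 CPM (log2 fold change −2.49). Of the C1q chains, which macrophages make, C1qb was slightly lower (log2 fold change −0.16, adjusted p = 0.00905), and C1qa and C1qc, at −0.03 and 0.02, did not pass (adjusted p = 0.605 and 0.809). Among 12 EGF family ligands and receptors 3 were higher and 3 lower, and Egfr, the main receptor by level, fell from 243 ± 5.35 to 199 ± 8.06 CPM (log2 fold change −0.29) while Ereg rose from 28.4 ± 1.74 to 47.0 ± 5.09 CPM (log2 fold change 0.72).

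Integrins changed subunit by subunit, with 9 of 23 higher and 10 lower. The fibronectin receptor chains Itga5 and Itgb1 rose from 1188 ± 17.1 to 3825 ± 9.39 CPM (log2 fold change 1.69) and from 2151 ± 24.6 to 3458 ± 42.5 CPM (log2 fold change 0.69), and Itga3 and Itga1 fell from 288 ± 11.2 to 169.8 ± 1.04 CPM (log2 fold change −0.76) and from 87.8 ± 0.176 to 46.9 ± 2.31 CPM (log2 fold change −0.90). In the Notch pathway, 7 of 15 were higher and 4 lower: the ligand Jag1 rose from 41.8 ± 1.28 to 397 ± 28.8 CPM (log2 fold change 3.25), the target Heyl from 0.191 ± 0.0322 to 6.76 ± 0.317 CPM (log2 fold change 5.11) and Notch4 from 3.88 ± 0.274 to 20.7 ± 1.04 CPM (log2 fold change 2.42), while Notch2 fell from 209.7 ± 2.20 to 157 ± 1.48 CPM (log2 fold change −0.42). Of 15 retinoid genes 7 were higher and 5 lower. The retinaldehyde dehydrogenases went opposite ways, with Aldh1a1 falling and Aldh1a3 rising as given in the report, Crabp2 rose from 1.88 ± 0.0391 to 8.49 ± 0.835 CPM (log2 fold change 2.17) and the retinoic acid hydroxylase Cyp26b1 fell from 7.30 ± 1.38 to 1.52 ± 0.255 CPM (log2 fold change −2.26). With library totals alone the retinoid counts were 5 and 5, and the Notch and integrin counts moved by at most 1.

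The mesothelial markers had a median log2 fold change of −1.83, and 3 of the 13 stand in another list. Fewer mesothelial cells with unchanged expression, as the only source of these transcripts, would lower all restricted markers by 1 factor. For 7 taken here as the most restricted (Upk3b, Upk1b, Lrrn4, Gpm6a, Muc16, Msln and Cldn15), log2 fold changes instead spanned 3.49. They ran from −1.52 for Msln (SE 0.115) to −5.02 for Muc16 (SE 0.157), with a median SE of 0.069. This spread argues against that explanation. With library totals the median was −1.93. That scaling shifts log2 fold changes by a median of −0.10 over all genes, so the run could not have removed the fall. It shows only that the choice between TMM and library totals does not account for the fall. Lower expression per cell under TGF-β1, or a loss of cells together with other sources of these transcripts, may each account for the fall and both stay open, since no cell counts were used here.

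The interferon genes were lower with TGF-β1 while control 2 stood a median of 0.76 above control 1. If control 2 alone carried the difference, it would vanish without that library. The median without control 2 was −0.68 (rounded from −0.6755), with 23 of 46 members still lower, short of the majority set in advance to argue against it. That remaining difference is no larger than the difference between the 2 controls. A lower interferon response under TGF-β1 and a raised one in the control cultures therefore cannot be told apart with 2 controls.

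Acta2 was slightly lower while Col1a1 rose. Reads moving to other actin genes are argued against, because those of Acta1, Actg2 and Actc1 that rose gained 70.0 CPM in sum against the 486 CPM by which Acta2 was lower. A ceiling on abundant genes was also examined. Of the 15 genes of like or higher abundance, 3 (Col1a1, Thbs1 and Fbln2) were higher by at least 0.3 in log2, and the others changed by less. This was the least number set to argue against a ceiling. Col1a1 belongs to the pattern itself, and without it the rule is not met. Thbs1 and Fbln2 still rose by 0.48 and 0.64 in log2, to levels above that of Acta2, which argues only against a ceiling at that level. Fewer smooth-muscle-like cells cannot be told apart from lower expression per cell: of 9 smooth-muscle genes 6 were lower, but 1 was called higher, Tagln.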
